A study of Mus musculus with 171 samples.

How the data were processed

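The data are log2 ratios, per the labels of RNA from a mouse tissue against a universal mouse reference RNA hybridised to the same 2-channel array, as deposited for 171 arrays with 8734 probes. Scanner software, background correction, dyes, normalization and builds are not given in the sources used here. The deposited values had been centred per probe: for 8709 probes (99.8%) the median over the arrays lay within 0.001 of 0, and 5 probes had no value. A ratio near 0 therefore means the usual level of that probe over all arrays, and levels of different probes were not compared. Medians of the arrays ran from -0.919 to 0.236, so the arrays were not scaled to a common median. The scale, the centring and the direction of the ratio stay unstated, and the report gives the likely reading.

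Probes were named through the platform annotation, updated by gene identifier to a table of mouse genes of the assembly GRCm38.p6, which was used for names only. A single symbol was found for 7540 probes, several for 14 and none for 1180. Named probes covered 5755 genes, 1423 of them with more than 1 probe. No 2 arrays held identical values, and all columns matched a sample. Array codes in the titles have 3 forms, on 69, 86 and 16 arrays, called the AC lot, the AF lot and the # form, with 13 finer series, and in 22 sources the arrays came from 2 lots. Of 166 arrays of sources with 2 arrays, 105 correlated best with the other array of their source.

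Before the data were examined, the groups, the 24 comparisons, the tests, the named-gene rule, 49 gene lists and most alternatives were fixed, and the exceptions are named in the closing section. Of 1234 genes on the lists, 423 had a probe, and 47 lists with at least 3 measured members were tested. Comparisons of single sources used limma 3.58.1 in R 4.3.3 on all arrays with 1 mean per source, which share an estimate of the spread. Nervous against other organs, tumours against normal intestine and small against large intestine used 1 mean per source as the unit, the intestinal ones with the title form as a covariate. Probes with at least 1 value per group and values on at least 80% of the units were tested, and adjusted p is by Benjamini-Hochberg over all tested probes with a threshold of 0.05. Beyond that, nothing corrects for both arrays of a source perhaps coming from 1 animal: p-values measure only the spread between these arrays, which may be technical. A lone array or source, left after leaving out others or by taking 1 lot or form, was assumed to vary like the other groups.

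Named genes had exactly 1 symbol and adjusted p under 0.05. One probe stood for each gene, that with values on the most arrays and then the lowest number. The 10 highest and 10 lowest were taken for 8 main comparisons and 4 and 4 for the others, for array comparisons only among genes with every array of the higher group above every array of the lower. For each list described up to 4 members with the largest change past the threshold were added, with no such condition. Of 1459 genes so taken over the array comparisons, 1436 had their arrays fully apart, and of the others the results describe only Myl7. Left out in turn were each array of an array comparison, each nervous source but none of the 28 others, each normal source but no tumour for small intestine tumours, and each source for large intestine tumours and for small against large intestine. Genes given in the report kept their call in these, unless stated otherwise. Clps, Ly6d and Kap in atrium and the cell cycle genes in liver at 6 h were retested so after their values were seen. Lists were tested with camera at a preset correlation of 0.01 (Benjamini-Hochberg over the lists of a comparison), against all other probes, with an estimated correlation as the alternative. The rule was to describe all lists past the threshold and those of the tissue. For length, the report keeps the 4 with the lowest p of each comparison and some lists of the tissue, and a part of the genes so taken, a choice made after their values were seen. Lists were not retested leaving arrays out. Of 178 list calls, 89 held with an estimated correlation. Permutation tests were two-sided with 100000 permutations.

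On simulated data with 200 changed probes among 8638, the steps recovered 70% of 2-fold and 95% of 4-fold changes for the ileum comparison, 74% and 100% for the nervous one, 60% and 95% for small intestine tumours and 38% and 91% for large intestine tumours. False calls were 11 of 176, 10 of 184, 6 of 161 and 8 of 137, for simulated data only. Alternatives were array medians centred, quantile normalization, lot and series as blocks, single lots or title forms, complete probes, averaged probes, only the arrays compared, the number shared by some tumour names as a random or fixed block, and leaving out arrays or sources. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.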

Results

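The series holds 171 spotted arrays of 88 mouse sources: normal organs, developing organs, tissues after injury, hormonal change or genetic manipulation, and intestinal tumours. Each array held RNA of a tissue and a universal mouse reference RNA, and the value of a probe is a log ratio of both. For 83 sources there were 2 arrays. Single arrays covered 5 sources, namely the tumours Duo59, Duo72 and Jej3, pancreatic islets and activated CD4 T cells. Each array gave 5137 to 8658 probe values (median 8638), and both arrays of a source correlated with r between 0.381 and 0.987 (median 0.869). The number of arrays limits the precision, and nothing in the labels says that both arrays of a source came from separate animals.

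Values in parentheses after a gene are log2 differences with the standard error of limma, positive where the tissue named first was higher. Members of a gene list not counted as higher or lower were not called. The direction and the log base are not stated in the sources. They were read as likely tissue over reference and log2, since 20 of 20 marker lists were higher in their own organ, 11 of them highest there of all sources, and the widest span of a probe, 13.48, would be a 716514-fold range with natural logs. Because each probe had been centred, 356 of 14535 pairs of arrays had r below -0.3. Turning the sign would swap the higher and lower counts of every comparison and leave sizes and tests. In the 10 comparisons where centring or quantile normalization moved the median of all probes by over 0.1, gene values are given after centring each array on its median, while values of other probes or with an array left out are as deposited.

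**Figure D1:**
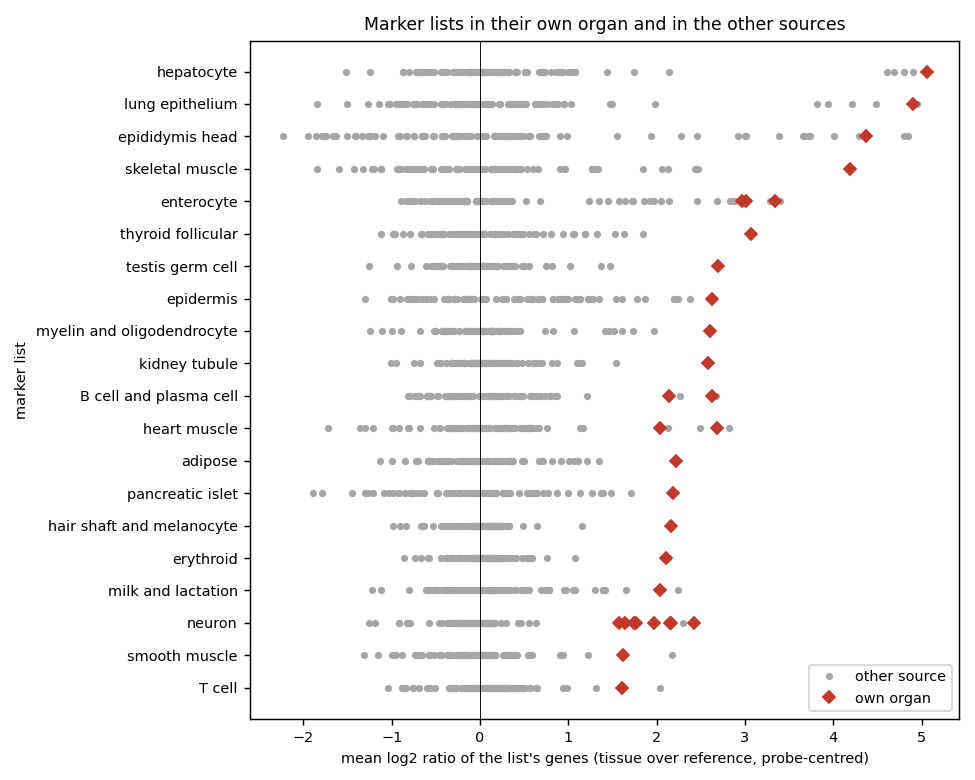
Mean log2 ratio (tissue over reference, each probe centred over the arrays) of the genes of 20 marker lists, with 1 point per source and diamonds for the organ of each list. The hepatocyte list averaged 5.06 in adult liver and 0.32 over the other sources, and the neuron list 1.93 in the nervous sources and -0.08 elsewhere.

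Nervous tissue (8 sources) was compared with 28 other adult sources. The myelin protein gene Mbp (5.97 ± 0.37), the neuronal membrane glycoprotein gene Gpm6a (5.40 ± 0.48), the synaptic vesicle calcium sensor Syt1 (4.96 ± 0.32) and the dendritic Map2 (4.47 ± 0.34) were among the highest. Kif1a (4.15 ± 0.24), an axonal transport motor, and Rab3a (3.91 ± 0.19), a regulator of vesicle release, lay above all other sources in 8 of 8 nervous sources, and Gpm6a and Map2 did so in 7 of 8. The epithelial immunoglobulin transporter Pigr (-3.56 ± 1.01) and keratin Krt19 (-3.44 ± 0.81) were lower, as was H2-Aa (-3.01 ± 0.51), a chain of the class II antigen receptor, though H2-Aa lay above all nervous sources in 17 of the 28 only. Of the marker groups, 10 of 13 neuron genes were higher (11 adjusted over the list alone, 10 with centring, camera adjusted p = 2.1e-25). Nefl (3.80 ± 0.34), a neurofilament chain, and Mapt (2.78 ± 0.30), the tau gene, were among them. For myelin, 3 of 6 genes were higher (4 adjusted over the list alone, 4 with centring, camera adjusted p = 1.4e-05), and for astrocytes 2 of 4 genes were higher (4 adjusted over the list alone, 4 with centring, camera adjusted p = 3.1e-05), including Aldoc (3.05 ± 0.23) and Fabp7 (2.49 ± 0.46). In the antigen presentation list, 7 of 11 genes were lower (9 adjusted over the list alone, 5 with centring, camera adjusted p = 0.0019, adjusted p = 0.82 with an estimated correlation). Of the heart muscle list, with no source left out, Csrp3 and Tnnt2 were called higher and Sln and Myh7 lower. limma called 1748 of 8638 probes, 784 higher and 964 lower. Centring array medians gave 1035 and 689 and quantile normalization 1001 and 583, moving the median of all probes by 0.11 and 0.10. Adjusted p was at most 0.0095 for genes with an SE.

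Normal small intestine (4 sources) was compared with normal large intestine (3 sources). Mttp (5.63 ± 0.38), which loads lipid onto lipoproteins, Rbp2 (4.09 ± 0.27), a retinol carrier of enterocytes, and the apolipoprotein genes Apob (2.79 ± 0.29) and Apoc3 (3.17 ± 0.52) were higher in small intestine, with the drug-metabolising Cyp3a11 (5.40 ± 0.53). In large intestine Hao2 (-5.10 ± 0.29), the carbonic anhydrase genes Car2 (-3.96 ± 0.44) and Car1 (-3.18 ± 0.45), and Guca2a (-3.33 ± 0.42), the guanylin precursor, were higher. 13 of 18 enterocyte genes were higher and 4 lower (13 and 4 adjusted over the list alone, camera adjusted p = 1.4e-17). Smooth muscle genes went with the large intestine: 3 of 8 genes were lower (4 adjusted over the list alone, camera adjusted p = 0.0043, adjusted p = 0.051 with an estimated correlation), with Cnn1 (-1.85 ± 0.30) and Flna (-0.94 ± 0.21). In the erythroid list 5 of 15 genes were lower (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.025), among them Car2 and Car1, which colon epithelium also makes, and in the hepatocyte list 3 of 16 genes were higher (4 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.08 with an estimated correlation). limma called 827 of 8494 probes, 434 higher and 393 lower, against 654 and 614 after quantile normalization. The genes with an SE had adjusted p up to 0.0057. The count was 467 without cecum, 418 without distal colon, 456 without proximal colon, 445 without duodenum and 450 without proximal jejunum.

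For tumours of the small intestine (10 sources) against normal small intestine (3 sources), Wfdc18 (3.67 ± 0.60), a whey acidic protein family gene, the interferon-induced membrane protein genes Ifitm3 (2.24 ± 0.27) and Ifitm2 (2.16 ± 0.36), and Ly6d (2.14 ± 0.34) were higher in 10 of 10 tumours than in every normal source. Lower in tumours were the enzymes Cyp2b10 (-3.11 ± 0.50) and Cyp4v3 (-2.31 ± 0.38), the tight junction gene Cldn15 (-1.91 ± 0.28) and the class I antigen gene H2-K1 (-1.77 ± 0.28). H2-K1 lay above all tumours in 1 of the 3 normal sources and Cldn15 in 2. 8 of 18 enterocyte genes were lower (12 adjusted over the list alone, camera adjusted p = 4e-09). The peptidase Dpp4 (-1.71 ± 0.34) stands for them, but was not called without proximal jejunum (-1.61, adjusted p = 0.091). In the list of Wnt targets 3 of 13 genes were higher (9 adjusted over the list alone, camera adjusted p = 1.7e-06). In the mitochondrial list 3 of 16 genes were lower (10 adjusted over the list alone, camera adjusted p = 9.5e-06, adjusted p = 0.22 with an estimated correlation), and 2 of the 3 measured astrocyte markers, Aldoc (0.78 ± 0.21) and Glul (1.08 ± 0.20), were higher (3 adjusted over the list alone, camera adjusted p = 0.00065). Aldoc was not called without any 1 of the 3 normal sources (0.63 to 0.93, adjusted p = 0.13 to 0.27) or after quantile normalization (0.87, adjusted p = 0.051), nor Glul without duodenum (1.06, adjusted p = 0.052) and without proximal jejunum (0.94, adjusted p = 0.084). limma called 329 of 8494 probes, 128 higher and 201 lower, against 119 and 62 after quantile normalization. For these genes adjusted p reached 0.045 at most. The count was 26 without duodenum, 33 without proximal jejunum and 1130 without proximal jejunum 46.

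In colon tumours (4 sources) against normal large intestine (3 sources), Wfdc18 (3.55 ± 0.72), Ifitm3 (2.16 ± 0.32) and Ly6d (2.41 ± 0.41) were higher, together with the protease inhibitor Slpi (2.46 ± 0.39), the immunoglobulin heavy chain locus Igh (2.82 ± 0.56) and the glycosyltransferase Gcnt2 (3.28 ± 0.39), for which 2 other probes gave -0.15 and 1.99. Lower were Hao2 (-3.88 ± 0.30), Guca2a (-3.86 ± 0.43), the sulfotransferase Sult1d1 (-3.84 ± 0.35), Car4 (-2.94 ± 0.55) and Car2 (-2.72 ± 0.46). Each of these lay beyond every source of the other group in all sources of its own. In the Wnt target list 4 of 13 genes were higher (8 adjusted over the list alone, camera adjusted p = 2.1e-07), with the transcription factor genes Sox4 (2.13 ± 0.38), Myc (1.39 ± 0.26) and Lef1 (1.19 ± 0.20), while another Sox4 probe gave -0.14. 7 of 16 mitochondrial genes were lower (11 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.2 with an estimated correlation), including Etfb (-1.58 ± 0.26) and Hadhb (-1.24 ± 0.20), which serve fatty acid oxidation. 5 of 18 enterocyte genes were lower (6 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.28 with an estimated correlation), with Fabp2 (-2.94 ± 0.59) among them. Of the goblet list, 1 of 7 genes was lower (2 adjusted over the list alone, camera adjusted p = 0.0036). Some smooth muscle and antigen presentation genes were lower as well: 2 of 8 genes were lower (2 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.19 with an estimated correlation) in the former list, with Cnn1 (-2.18 ± 0.31), and 2 of 11 genes were lower (3 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.41 with an estimated correlation) in the latter, with H2-K1 (-2.66 ± 0.33). limma called 448 of 8494 probes, 208 higher and 240 lower, against 697 and 471 after quantile normalization. Of the genes given, the weakest had an adjusted p of 0.0044. The count was 192 without cecum, 289 without distal colon and 279 without colon tumour Col2.

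**Figure D2:**
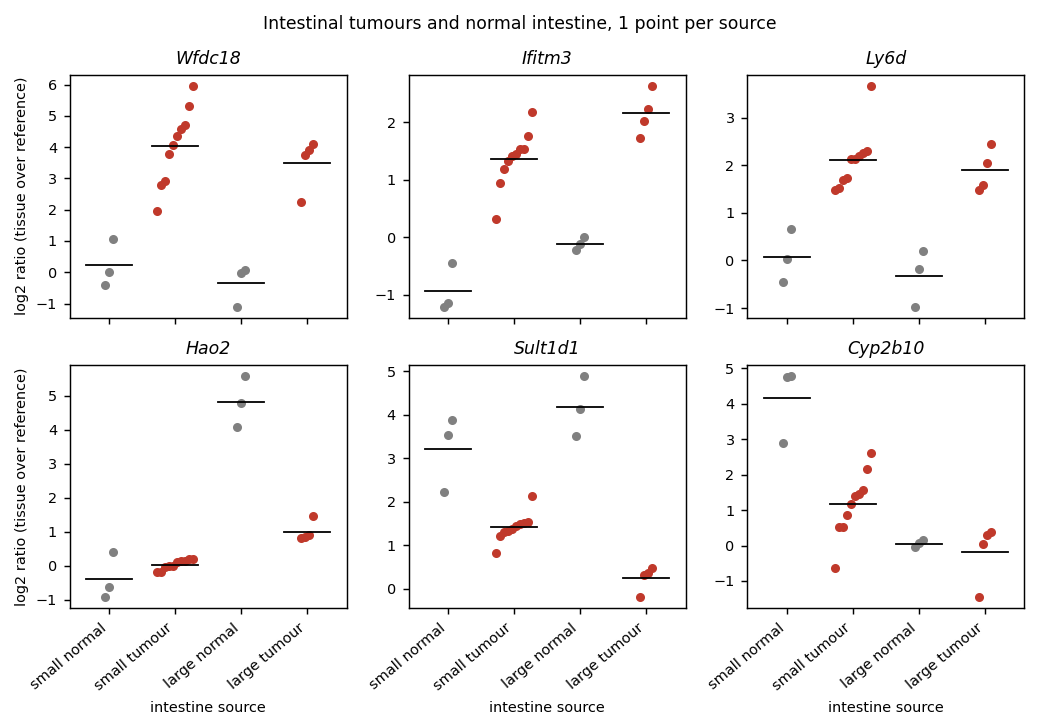
Mean log2 ratio (tissue over reference) of 6 genes in each source of normal and tumour intestine, with 1 point per source and a line at the mean of each group. Wfdc18, Ifitm3 and Ly6d were higher in both kinds of tumour, and Hao2 was lower in large intestine tumours (-3.88 ± 0.30, standard error).

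Ileum after bowel resection was set against ileum after a sham operation (2 arrays each). Angptl4 (1.34 ± 0.28), an inhibitor of lipoprotein lipase, was higher. Fgf15 (-1.49 ± 0.24), the ileal hormone that restrains bile acid synthesis, was lower. Fgf15 was not called without ileum sham resection replicate 2 (-1.02, adjusted p = 0.3). Angptl4 was not called without any 1 of the 4 arrays (1.25 to 1.42, adjusted p = 0.068 to 0.28). The interferon response list went lower as a group (camera adjusted p = 0.00071, adjusted p = 0.12 with an estimated correlation) with 0 of 14 genes called by limma and 3 lower at an unadjusted p under 0.05. Antigen presentation likewise went lower (camera adjusted p = 0.0023, adjusted p = 0.62 with an estimated correlation), with 0 of 11 called and 2 lower at an unadjusted p under 0.05, and adjusted over the list alone each of these lists had 1 lower. The extracellular matrix list went higher (camera adjusted p = 0.0023, adjusted p = 0.62 with an estimated correlation), with 0 of 21 called by limma and 1 higher and 1 lower at an unadjusted p under 0.05, and so did the erythroid list (camera adjusted p = 0.048, adjusted p = 0.38 with an estimated correlation), with 0 of 15 called by limma and 1 higher at an unadjusted p under 0.05, both with 0 adjusted over the list alone. limma called 14 of 8638 probes, 7 higher and 7 lower, while only these arrays gave 0 (231 at an unadjusted p under 0.05). Up to 0.0085 was the adjusted p of the named genes. The count was 9 without ileum sham resection replicate 1 and 2 without ileum sham resection replicate 2. After quantile normalization limma called 0, with 233 at an unadjusted p under 0.05.

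Liver 6 h into regeneration was compared with liver 6 h after a sham operation (2 arrays each). Igfbp1 (2.44 ± 0.44), a secreted binder of insulin-like growth factors made by hepatocytes, the acute phase protein gene Orm1 (1.65 ± 0.25), and Mrap (2.48 ± 0.45), an accessory protein of the corticotropin receptor, were higher. Rpa2 (2.52 ± 0.22), of the DNA-binding replication protein A, was higher and Xrcc1 (-2.03 ± 0.28), a DNA repair gene, lower, with -0.07 for its other probe. 2 of 7 acute phase genes were higher (3 adjusted over the list alone, 2 with centring, camera adjusted p = 0.0022). Of the immediate early list, 2 of 9 genes were higher (2 adjusted over the list alone, 2 with centring, camera adjusted p = 0.0054, adjusted p = 0.11 with an estimated correlation), namely Zfp36 (0.96 ± 0.19), which destabilises messenger RNA, and the phosphatase gene Dusp1 (1.12 ± 0.23), not called without liver regeneration 6 h replicate 1 (0.84, adjusted p = 0.089). 4 of 28 cell cycle genes were lower (5 adjusted over the list alone, 1 with centring, camera adjusted p = 0.4, adjusted p = 0.98 with an estimated correlation), and each lost its call without 1 or more arrays, Mcm2 without liver regeneration 6 h replicate 1 (-0.38, adjusted p = 0.51). Over 20 marker lists, this source had the lowest mean of all sources for 7, and for 2 with array medians, -0.92 and -0.61 here, centred. limma called 690 of 8638 probes, 132 higher and 558 lower, against 194 and 277 with array medians centred and 13 and 6 after quantile normalization, while only these arrays gave 0 (1242 at an unadjusted p under 0.05), and the median of all probes moved by 0.13 with centring and 0.12 with quantile normalization. Adjusted p was at most 0.0004 for genes with an SE. The count was 224 without liver regeneration 6 h replicate 1, 281 without liver sham 6 h replicate 1 and 228 without liver sham 6 h replicate 2. With the array series as a block the count was 290, and Zfp36 was not called (0.77, adjusted p = 0.082). Quantile normalization ended the calls of Igfbp1 (0.87, adjusted p = 1), Orm1 (0.62, adjusted p = 0.63), Mrap (1.03, adjusted p = 0.73), Dusp1 (0.54, adjusted p = 0.67) and Zfp36 (0.53, adjusted p = 0.62).

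Liver 24 h into regeneration was compared with adult fed liver (2 arrays each), with no sham to set surgery and feeding apart. The acute phase genes Orm1 (2.22 ± 0.25) and Apcs (2.71 ± 0.37), Lrg1 (2.38 ± 0.22), the cell cycle inhibitor Cdkn1a (3.00 ± 0.21) and Ly6d (4.89 ± 0.47) were higher. The sulfotransferase Sult2a8 (-2.60 ± 0.38) and the steroid dehydrogenase Hsd3b1 (-2.42 ± 0.31) were lower. A probe for Ndufs1 (4.18 ± 0.22), of mitochondrial complex I, was higher while its other probes gave -0.44 and 0.13. 5 of 7 acute phase genes were higher (5 adjusted over the list alone, 5 with centring, camera adjusted p = 2.2e-10). In the kidney injury list, which holds general stress genes such as Cdkn1a, 4 of 16 genes were higher and 1 lower (5 and 1 adjusted over the list alone, 5 higher and 1 lower with centring, camera adjusted p = 2.6e-05). 4 of 13 ribosomal protein genes were higher and 1 lower (5 and 1 adjusted over the list alone, 5 with centring, camera adjusted p = 0.0023, adjusted p = 0.19 with an estimated correlation), with Rplp2 (1.14 ± 0.18) among them. The epidermis list passed with 1 of 8 genes called, Ly6d (1 adjusted over the list alone, 1 with centring, camera adjusted p = 0.0068, adjusted p = 0.12 with an estimated correlation). In the mammary involution list the median member differed by -0.01 and the mean by 0.28 while the test went up (camera adjusted p = 0.039). limma called 1208 of 8638 probes, 222 higher and 986 lower, while only these arrays gave 110. Centring array medians gave 421 and 282 and quantile normalization 78 and 28, moving the median of all probes by 0.20 and 0.23. The genes given had adjusted p up to 1.6e-06. The count was 520 without liver adult fed replicate 1, 492 without liver adult fed replicate 2 and 791 without liver regeneration 24 h replicate 2.

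Fetal liver at embryonic day 14, when the organ forms blood, was compared with adult liver (2 arrays each). Genes of the red cell line were far higher: the globin gene Hba-a1 (6.94 ± 1.01), the red cell anion exchanger Slc4a1 (5.71 ± 0.43), Cd24a (7.02 ± 0.20), Car2 (4.90 ± 0.30) and the transcription factor gene Nfe2 (3.85 ± 0.36). 13 of 15 erythroid genes were higher (13 adjusted over the list alone, 12 higher and 1 lower with centring, camera adjusted p = 7e-07). Igf2 (5.15 ± 0.45) and the imprinted Grb10 (4.82 ± 0.38) were higher, but their list, of fetal growth and imprinted genes, had 5 of 8 genes higher and 3 lower (5 and 3 adjusted over the list alone, 4 and 3 with centring) and did not pass as a group (camera adjusted p = 0.29). Lower in fetal liver were Tdo2 (-7.40 ± 0.34), which degrades tryptophan, Hamp (-6.79 ± 0.39), the hepcidin gene, the carboxylesterase Ces1c (-7.33 ± 0.42) and Cyp3a11 (-6.06 ± 0.62). 12 of 16 hepatocyte genes were lower (12 adjusted over the list alone, 13 with centring, camera adjusted p = 4.8e-08). Of the cell cycle list 23 of 28 genes were higher (23 adjusted over the list alone, 22 higher and 1 lower with centring, camera adjusted p = 2e-16), with the replication helicase genes Mcm6 (3.93 ± 0.25) and Mcm5 (3.58 ± 0.24). 11 of 13 ribosomal protein genes were higher and 2 lower (11 and 2 adjusted over the list alone, 10 higher and 2 lower with centring, camera adjusted p = 0.00081, adjusted p = 0.14 with an estimated correlation), Rpl3 (1.89 ± 0.19) and Rpl4 (-2.45 ± 0.42) going opposite ways. Probes for Tmem185a (6.66 ± 0.24), Mrps18b (5.27 ± 0.26), Timm17a (5.15 ± 0.66) and Kansl3 (5.12 ± 0.77) were among the highest, with second probes at -0.31 (Mrps18b) and 0.49 (Kansl3) as deposited. Over the 87 other sources all 4 correlated with the Hba-a1 probe (Pearson's r 0.75 to 0.95, Spearman's rho 0.59 to 0.86, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 2e-05, and r 0.62 to 0.92 without the 2 farthest sources). limma called 5282 of 8638 probes, 3340 higher and 1942 lower. Centring array medians gave 2042 and 3307 and quantile normalization 1970 and 1759, moving the median of all probes by -0.40 and -0.24. For these genes adjusted p reached 7.1e-07 at most.

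Lung at embryonic day 13.5 was compared with adult lung (2 arrays each). The surfactant protein genes Sftpc (-5.86 ± 0.60) and Sftpb (-5.86 ± 0.45), the club cell genes Scgb1a1 (-5.35 ± 0.58) and Cyp2f2 (-6.70 ± 0.82), and the fatty acid receptor Cd36 (-5.82 ± 0.46), abundant in capillary endothelium, were lower in the embryo. The embryonic tight junction gene Cldn6 (4.71 ± 0.42), the growth factor gene Mdk (3.32 ± 0.27) and the imprinted genes Grb10 (3.97 ± 0.37) and Igf2 (3.24 ± 0.44) were higher. Other probes gave -1.67 for Scgb1a1 and 0.68 for Igf2. 6 of 6 lung epithelial genes were lower (6 adjusted over the list alone, camera adjusted p = 1.2e-17). 20 of 28 cell cycle genes were higher (20 adjusted over the list alone, camera adjusted p = 1.6e-25). Racgap1 (3.39 ± 0.25) and Mcm6 (3.00 ± 0.24) were among them, and Kif20a (3.66 ± 0.27) was higher by one probe and at -0.13 by another. Antigen presentation genes were lower in the embryo: 6 of 11 genes were lower (6 adjusted over the list alone, camera adjusted p = 7.7e-10), with H2-Aa (-4.07 ± 0.40) and H2-D1 (-2.52 ± 0.19). In the adipose list 8 of 13 genes were lower (8 adjusted over the list alone, camera adjusted p = 4.1e-07), Cd36 and Gpd1 (-2.28 ± 0.28) among them. limma called 1701 of 8638 probes, 1170 higher and 531 lower, against 1434 and 1179 after quantile normalization, while only these arrays gave 622. Of the genes given, the weakest had an adjusted p of 5.6e-09. The count was 1040 without lung adult replicate 1.

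Across 8 stages from embryonic day 13.5 to adult (16 arrays), values are log2 slopes per stage. The slopes were positive for Cyp2f2 (0.91 ± 0.09), Scgb1a1 (0.85 ± 0.06), Cd36 (0.81 ± 0.05), H2-Aa (0.69 ± 0.04), Sftpc (0.68 ± 0.07) and Sftpb (0.64 ± 0.05), and negative for Cldn6 (-0.65 ± 0.05), Grb10 (-0.57 ± 0.04), Igf2 (-0.53 ± 0.05) and the cytokinesis gene Racgap1 (-0.40 ± 0.03). Other probes gave 0.22 for Scgb1a1 and -0.12 for Igf2. Sftpc went from 1.35 ± 0.50 (SD, n = 2) at embryonic day 13.5 to 6.83 ± 0.19 (SD, n = 2) at embryonic day 18.5, while Scgb1a1 went from 0.60 ± 0.25 to 2.85 ± 0.05 and reached 5.95 ± 0.44 in the adult. Racgap1 was at 0.03 ± 0.06 on postnatal day 1 and 1.19 ± 0.05 on day 5. 6 of 6 lung epithelial genes were higher (6 adjusted over the list alone, camera adjusted p = 2.1e-17). 6 of 11 antigen presentation genes were higher (8 adjusted over the list alone, camera adjusted p = 5.8e-16). 20 of 28 cell cycle genes were lower (20 adjusted over the list alone, camera adjusted p = 3.9e-23). 5 of 8 genes of the fetal growth list were lower (5 adjusted over the list alone, camera adjusted p = 7.9e-08). limma called 1969 of 8638 probes, 704 higher and 1265 lower, against 1436 and 1675 after quantile normalization. Up to 1.1e-14 was the adjusted p of the named genes.

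**Figure D3:**
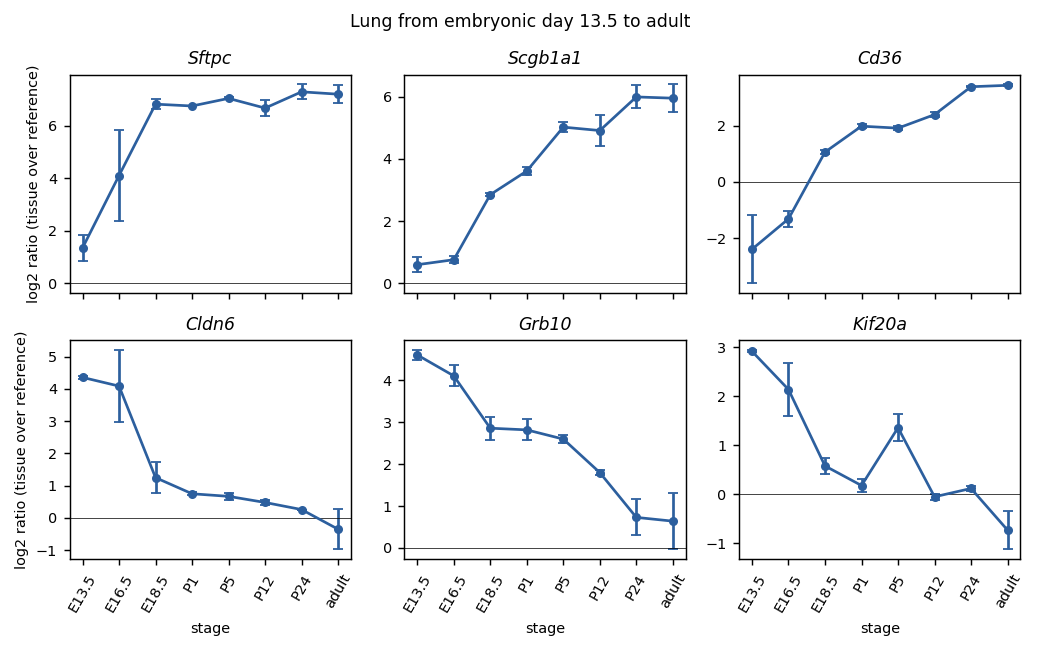
Log2 ratio (tissue over reference) of 6 genes in lung at 8 stages, as mean and SD of both arrays (1 array for Sftpc on postnatal day 1 and Cldn6 on day 24, drawn without a bar). Sftpc rose between embryonic days 13.5 and 18.5, Scgb1a1 and Cd36 were higher in the adult than on day 18.5, Cldn6 and Grb10 went down, and Kif20a went from 2.92 ± 0.02 on day 13.5 to 0.18 ± 0.13 on postnatal day 1, 1.36 ± 0.27 on day 5 and -0.73 ± 0.39 in the adult.

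Kidney after folic acid, which injures renal tubules, was compared with adult kidney (2 arrays each). The lipopolysaccharide co-receptor Cd14 (3.97 ± 0.42), the fibrinogen chain Fgb (2.69 ± 0.40), the phosphate transporter Slc20a1 (3.35 ± 0.24), heme oxygenase Hmox1 (2.17 ± 0.20) and Myc (1.59 ± 0.22) were higher. Enzymes and transporters of the proximal tubule were lower: Miox (-3.02 ± 0.27), Slc34a3 (-3.34 ± 0.34), Gatm (-3.52 ± 0.49), Hao2 (-4.16 ± 0.30) and Slc27a2 (-2.68 ± 0.39). Immunoglobulin Igh (-4.10 ± 0.40) and class II H2-Aa (-2.69 ± 0.38) were lower also. 10 of 14 kidney tubule genes were lower (10 adjusted over the list alone, 10 with centring, camera adjusted p = 5.5e-24). 10 of 16 kidney injury genes were higher (11 adjusted over the list alone, 8 with centring, camera adjusted p = 4.1e-15), with Ccn1 (2.00 ± 0.27) as another example. 1 of 17 mitochondrial genes was higher and 7 lower (1 and 8 adjusted over the list alone, 1 higher and 7 lower with centring, camera adjusted p = 1.7e-06, adjusted p = 0.34 with an estimated correlation), Acadm (-2.38 ± 0.22) being lower and 1 probe of Ndufs1 (1.16 ± 0.22) higher, with -0.01 and 0.11 for its other probes. In the mammary involution list 4 of 12 genes were higher (6 adjusted over the list alone, 4 with centring, camera adjusted p = 5.6e-05), among them Cd14, Bcl3 (2.33 ± 0.32) and Stat3 (1.31 ± 0.20), genes of inflammatory signalling. limma called 766 of 8638 probes, 503 higher and 263 lower, while only these arrays gave 2. Centring array medians gave 315 and 349 and quantile normalization 712 and 541, moving the median of all probes by -0.12 and -0.15. Adjusted p was at most 5.3e-05 for genes with an SE. The count was 493 without kidney adult replicate 1 and 473 without kidney folic acid replicate 2.

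Kidney at embryonic day 18.5 against adult kidney (2 arrays each) had higher Fstl1 (4.76 ± 0.37), a secreted glycoprotein gene, Cldn6 (4.22 ± 0.41), Cd24a (2.22 ± 0.20) and the replication origin gene Orc5 (3.97 ± 0.28). Proximal tubule genes were lower, such as the dicarboxylate transporter Slc13a3 (-3.48 ± 0.27), Slc27a2 (-3.38 ± 0.39), Miox (-2.97 ± 0.27) and Kap (-2.58 ± 0.28), the androgen-regulated kidney protein gene. 11 of 14 kidney tubule genes were lower (11 adjusted over the list alone, 11 with centring, camera adjusted p = 4.9e-13). 15 of 28 cell cycle genes were higher (18 adjusted over the list alone, 14 with centring, camera adjusted p = 7e-12), with Racgap1 (3.54 ± 0.26) among them. 9 of 13 ribosomal protein genes were higher (9 adjusted over the list alone, 9 with centring, camera adjusted p = 1.9e-13), Rps15 (2.35 ± 0.19) and Rpl7 (2.29 ± 0.17) among them. In the kidney injury list, which includes Cd24a, 9 of 16 genes were higher and 1 lower (12 and 1 adjusted over the list alone, 9 higher and 1 lower with centring, camera adjusted p = 1.8e-05). limma called 2316 of 8638 probes, 1903 higher and 413 lower, against 1560 and 973 with array medians centred and 1651 and 2196 after quantile normalization, while only these arrays gave 1188, and the median of all probes moved by -0.12 with centring and -0.18 with quantile normalization. The genes given had adjusted p up to 1.5e-11. The count was 1368 without kidney adult replicate 1.

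Hearts of a transgenic model that the labels call hyperdynamic were compared with their controls (2 arrays each). The natriuretic peptide genes Nppa (4.64 ± 0.48) and Nppb (1.71 ± 0.40), secreted by stressed heart muscle, and the matrix genes Thbs4 (2.60 ± 0.50) and Postn (2.19 ± 0.33) were higher. Ucp3 (-2.49 ± 0.35), a mitochondrial uncoupling protein gene, Pdk4 (-2.37 ± 0.38), which restrains glucose oxidation, and Ces1d (-3.30 ± 0.40), a lipase, were lower, as were the fatty acid oxidation genes Hadhb (-1.48 ± 0.22) and Acadm (-1.46 ± 0.22). 5 of 10 cardiac stress genes were higher (7 adjusted over the list alone, 5 with centring, camera adjusted p = 2.4e-09). 13 of 17 mitochondrial genes were lower (14 adjusted over the list alone, 14 with centring, camera adjusted p = 1.2e-18). 2 of 5 atrial genes were higher (2 adjusted over the list alone, 2 with centring, camera adjusted p = 0.0016), Nppa and Dkk3 (0.96 ± 0.24), the latter not called after quantile normalization (0.64, adjusted p = 0.082). 5 of 21 extracellular matrix genes were higher (9 adjusted over the list alone, 3 with centring, camera adjusted p = 0.0066, adjusted p = 0.56 with an estimated correlation). The control hearts had the lowest mean of all sources for 5 of 20 marker lists, and for 2 with array medians, -0.78 and -0.45 here, centred. limma called 991 of 8638 probes, 760 higher and 231 lower, while only these arrays gave 19. Centring array medians gave 435 and 652 and quantile normalization 90 and 50, moving the median of all probes by -0.18 and -0.14. For these genes adjusted p reached 0.0037 at most. The count was 359 without heart hyperdynamic control replicate 1 and 376 without heart transgenic hyperdynamic replicate 2.

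Atrium was compared with ventricle (2 arrays each). Higher in atrium were Sln (5.15 ± 0.49), a regulator of the calcium pump, Nppa (4.96 ± 0.48) and Dkk3 (3.80 ± 0.24), with the matrix gene Fn1 (2.45 ± 0.30) and the lipid synthesis gene Fasn (2.63 ± 0.32). Sdhb (-3.21 ± 0.39), of the respiratory chain, was lower. Fn1, 2.54 as deposited, was 1.34 without heart atrium replicate 2. Sdhb, -3.12 as deposited, was -0.85 without heart atrium replicate 2 and -5.39 without replicate 1. Fasn, 2.72 as deposited, was 1.32 without heart atrium replicate 1 and 4.12 without replicate 2. The 2 atrial arrays had an SD of 1.70 for Fn1, 3.21 for Sdhb and 1.98 for Fasn, as deposited. The standard errors of these genes rest on all arrays and understate this spread. 4 of 5 atrial genes were higher (4 adjusted over the list alone, 4 with centring, camera adjusted p = 1e-28). The atrial light chain Myl7 (1.46 ± 0.48) was called higher, but its 2 atrial arrays did not both lie above the ventricular ones, and it was not called without heart atrium replicate 1 (-0.42, adjusted p = 0.84), without heart ventricle replicate 1 (1.48, adjusted p = 0.13) and without heart ventricle replicate 2 (1.62, adjusted p = 0.17), against a higher value without heart atrium replicate 2 (3.52, adjusted p = 2.4e-07). 10 of 17 mitochondrial genes were lower (12 adjusted over the list alone, 11 with centring, camera adjusted p = 4.6e-16). 2 of 10 cardiac stress genes were higher (4 adjusted over the list alone, 2 with centring, camera adjusted p = 8.9e-06). 5 of 21 extracellular matrix genes were higher (9 adjusted over the list alone, 3 with centring, camera adjusted p = 3.6e-05, adjusted p = 0.19 with an estimated correlation). 3 of 13 adipose genes were higher (4 higher and 1 lower adjusted over the list alone, 3 with centring, camera adjusted p = 0.013, adjusted p = 0.14 with an estimated correlation), namely Fasn, Gpd1 and Cidea (1.70 ± 0.50), the last not called without heart atrium replicate 2 (1.78, adjusted p = 0.25) and without heart ventricle replicate 2 (1.64, adjusted p = 0.14). Of lists that did not pass, the acinar gene Clps (2.24) and the epidermal Ly6d (1.88) were called higher and the tubule gene Kap (-1.05) lower, as deposited. Without heart atrium replicate 2 they gave 0.97, 0.46 and -0.16 (adjusted p = 1 for each), without replicate 1 3.51, 3.29 and -1.94, and without heart ventricle replicate 2 2.21, 1.69 and -0.96 (adjusted p = 0.067, 0.078 and 0.13). limma called 731 of 8638 probes, 467 higher and 264 lower, against 326 and 384 with array medians centred and 406 and 498 after quantile normalization, while only these arrays gave 6, and the median of all probes moved by -0.09 with centring and -0.11 with quantile normalization. Of the genes given, the weakest had an adjusted p of 0.043. The count was 1353 without heart atrium replicate 1, 59 without heart atrium replicate 2 and 248 without heart ventricle replicate 2.

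Synovium, the lining of joints, was compared between acute arthritis and normal joints (2 arrays each). Slpi (3.76 ± 0.37), the matrix genes Col1a1 (3.37 ± 0.36), Lum (3.35 ± 0.39) and Postn (3.17 ± 0.32), the lysosomal protease Ctss (3.18 ± 0.35), the osteoclast and macrophage phosphatase Acp5 (3.11 ± 0.31) and the complement gene Cfb (2.94 ± 0.28) were higher. The Fc receptor Fcgr2b (2.93 ± 0.23) and Angptl4 (3.18 ± 0.28) were higher as well. 13 of 21 extracellular matrix genes were higher (17 adjusted over the list alone, camera adjusted p = 5.2e-25). 4 of 9 matrix remodelling genes were higher (4 adjusted over the list alone, camera adjusted p = 1.2e-08), Mmp2 (2.71 ± 0.31) and Timp2 (2.03 ± 0.21) among them, a further Timp2 probe giving 0.83. 7 of 13 macrophage genes were higher (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.1e-12), such as Mpeg1 (2.74 ± 0.50). 5 of 10 neutrophil and inflammation genes were higher (7 adjusted over the list alone, camera adjusted p = 1.2e-08), with S100a8 (2.71 ± 0.22) and the granule genes Ltf (2.51 ± 0.46) and Camp (2.43 ± 0.42). The lower genes were less firm: each of the 10 lowest lost its call without 1 or more of the arrays. The skeletal muscle list averaged 1.85 ± 0.06 in acute arthritis and 2.13 ± 0.02 in normal joints (SD, n = 2). limma called 783 of 8638 probes, 731 higher and 52 lower, against 1072 and 476 after quantile normalization, while only these arrays gave 4722. Up to 2.5e-05 was the adjusted p of the named genes. The count was 367 without synovium acute arthritis replicate 1, 460 without synovium acute arthritis replicate 2, 385 without synovium normal replicate 1 and 403 without synovium normal replicate 2.

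In chronic arthritis against the same normal synovium (2 arrays each), Col1a1 (3.87 ± 0.36), Fn1 (3.24 ± 0.29), Lum (3.17 ± 0.39), Comp (2.28 ± 0.36) and Col6a1 (2.59 ± 0.23), all matrix genes, were higher, together with the bone phosphatase Alpl (2.21 ± 0.42), at 0.19 by another probe, and Acp5 (2.22 ± 0.31). Fhl1 (-1.62 ± 0.34), abundant in skeletal muscle, was lower, while the skeletal muscle list averaged 2.47 ± 0.14 (SD, n = 2). 12 of 21 extracellular matrix genes were higher (14 adjusted over the list alone, camera adjusted p = 5.6e-34). 4 of 9 matrix remodelling genes were higher (4 adjusted over the list alone, camera adjusted p = 9.2e-10), with Mmp2 (3.08 ± 0.31) and Timp2 (2.48 ± 0.21). 5 of 8 cartilage and bone genes were higher (5 adjusted over the list alone, camera adjusted p = 1.4e-08). In the kidney injury list 3 of 16 genes were higher (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.8e-05), Fn1 and Anxa2 (1.10 ± 0.22) among them. limma called 330 of 8638 probes, 264 higher and 66 lower, against 405 and 244 after quantile normalization, while only these arrays gave 1116. Adjusted p was at most 0.00077 for genes with an SE. The count was 155 without synovium chronic arthritis replicate 1, 189 without synovium chronic arthritis replicate 2, 141 without synovium normal replicate 1 and 143 without synovium normal replicate 2.

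Lymph node after adjuvant stimulation, which provokes an immune response, was compared with unstimulated node (2 arrays each). Immunoglobulin Igh (2.81 ± 0.42), Slpi (2.78 ± 0.37) and the collagen gene Col1a1 (2.59 ± 0.36) were higher, Igh without a call after quantile normalization (0.38, adjusted p = 0.52). The kinase Pdk1 (-3.97 ± 0.43), the splicing factor gene Sf3b1 (-2.84 ± 0.20) and the actin regulator Dstn (-2.81 ± 0.28) were lower. 8 of 10 neutrophil and inflammation genes were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0016), with S100a8 (2.19 ± 0.22) and Camp (1.84 ± 0.42). Probes of Lcn2, on this list, were called in both directions. 7 of 13 adipose genes were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.00093), and 4 of 6 genes of the milk list were higher (4 adjusted over the list alone, camera adjusted p = 0.00093). These lists share the lipid synthesis genes Acaca (2.38 ± 0.16) and Fasn (2.31 ± 0.32), and the fat droplet gene Cidec (2.37 ± 0.34) was higher too. The adipose list averaged 0.35 ± 0.02 in stimulated and -0.57 ± 0.10 in unstimulated node (SD, n = 2). 9 of 21 extracellular matrix genes were higher (9 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.65 with an estimated correlation). Of the B cell and plasma cell list, 1 of 8 genes was called higher (0 adjusted over the list alone, camera adjusted p = 0.97). limma called 3445 of 8638 probes, 1899 higher and 1546 lower, against 1182 and 920 after quantile normalization, while only these arrays gave 622. The genes given had adjusted p up to 0.00024. The unstimulated arrays belong to 1 array series and the stimulated arrays to 2 others, and with the series as a random block the count was 3246.

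Lactating mammary gland was compared with the gland in involution, its regression after lactation (2 arrays each). Pdk1 (4.42 ± 0.42) and Cidea (3.00 ± 0.50), a lipid droplet gene, were higher in lactation. Slpi (-5.71 ± 0.39), Angptl4 (-4.51 ± 0.29), Pdk4 (-4.24 ± 0.38) and Cd14 (-4.16 ± 0.42) were lower, as were the fatty acid oxidation genes Acadm (-2.31 ± 0.22) and Hadhb (-1.58 ± 0.22). 13 of 17 mitochondrial genes were lower (15 adjusted over the list alone, 1 higher and 12 lower with centring, camera adjusted p = 0.00018, adjusted p = 0.9 with an estimated correlation), a call missed with all probes of the list (adjusted p = 0.052). The mammary involution list, with Cd14 and Stat3, had 1 of 12 genes higher and 8 lower (1 and 8 adjusted over the list alone), and the milk list 2 of 6 higher and 2 lower (3 and 2 adjusted over the list alone), but neither passed as a group (camera adjusted p = 0.43 and 0.61). The milk list had its highest mean of all sources in the involuting gland (2.25 ± 0.00, SD, n = 2) and its second highest in the lactating gland (2.04 ± 0.06, SD, n = 2). limma called 3719 of 8638 probes, 588 higher and 3131 lower, against 2475 and 2299 with array medians centred and 614 and 982 after quantile normalization, while only these arrays gave 5765, and the median of all probes moved by 0.32 with centring and 0.28 with quantile normalization. For these genes adjusted p reached 5.5e-07 at most.

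Uterus on day 4.5 of pregnancy, around implantation, was compared with virgin uterus in diestrus (2 arrays each). Keratinocyte genes were higher, namely Krt13 (2.70 ± 0.49), Krt6a (2.51 ± 0.45), Sprr1a (1.25 ± 0.23) and Ly6d (3.00 ± 0.45). The growth factor gene Igf1 (1.25 ± 0.19) was higher, and the nuclear receptor Nr4a1 (-2.35 ± 0.24) and the fatty acid binding gene Fabp7 (-2.70 ± 0.53) were lower. 4 of 8 epidermis genes were higher (4 adjusted over the list alone, camera adjusted p = 2.7e-07). 9 of 28 cell cycle genes were higher (12 adjusted over the list alone, camera adjusted p = 1.5e-10), with Racgap1 (2.08 ± 0.25) and Mad2l1 (1.37 ± 0.28). 3 of 4 islet genes were lower (3 adjusted over the list alone, camera adjusted p = 0.0037), among them Sst (-1.38 ± 0.29), the somatostatin gene, not called without uterus pregnant day 4.5 replicate 2 (-1.13, adjusted p = 0.075). 3 of 17 mitochondrial genes were higher (3 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.47 with an estimated correlation), a call missed with all probes of the list (adjusted p = 0.059). 2 of 13 uterine hormone response genes were higher (3 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.3 with an estimated correlation), Igf1 and Ltf (1.81 ± 0.46). Ltf was not called without uterus pregnant day 4.5 replicate 2 (1.80, adjusted p = 0.083) and without uterus virgin diestrus replicate 2 (1.73, adjusted p = 0.072), nor after quantile normalization (0.76, adjusted p = 0.28). limma called 857 of 8638 probes, 239 higher and 618 lower, against 389 and 526 with array medians centred and 671 and 764 after quantile normalization. Of the genes with an SE, the weakest had an adjusted p of 0.0051. The count was 139 without uterus pregnant day 4.5 replicate 2, 377 without uterus virgin diestrus replicate 1 and 272 without uterus virgin diestrus replicate 2.

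Virgin uterus in estrus against diestrus (2 arrays each) had higher Ltf (3.44 ± 0.48), the estrogen-induced lactoferrin gene, not called after quantile normalization (0.76, adjusted p = 0.29), the complement gene Cfb (3.11 ± 0.31), Alpl (3.28 ± 0.43) and Clca1 (2.93 ± 0.39), a second probe of which gave -1.06. Tgfbi (-2.70 ± 0.22), a matrix gene, and the mast cell genes Hdc (-2.73 ± 0.44) and Cma1 (-2.46 ± 0.48) were lower. In the islet list 3 of 4 genes were lower (3 adjusted over the list alone, 2 with centring, camera adjusted p = 0.0084, adjusted p = 0.17 with an estimated correlation), with Sst (-1.96 ± 0.28) and the neuroendocrine Scg3 (-1.70 ± 0.32). 2 of 17 mitochondrial genes were higher (3 adjusted over the list alone, 4 with centring, camera adjusted p = 0.0084, adjusted p = 0.58 with an estimated correlation). The milk list passed with 1 of 6 genes called, Ltf (1 adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.17 with an estimated correlation). Of the uterine hormone response list 3 of 13 genes were higher and 3 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.062). limma called 1305 of 8638 probes, 244 higher and 1061 lower. Centring array medians gave 503 and 653 and quantile normalization 673 and 901, moving the median of all probes by 0.19 and 0.16. Up to 7.7e-05 was the adjusted p of the genes with an SE. The count was 863 without uterus virgin diestrus replicate 1, 588 without uterus virgin diestrus replicate 2 and 521 without uterus virgin estrus replicate 1.

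The head of the epididymis, where sperm enter, was compared with its tail, where they are stored (2 arrays each). The tight junction gene Cldn2 (3.71 ± 0.35), the heparan sulfate enzyme Hs3st3a1 (3.37 ± 0.26) and Cryba4 (3.15 ± 0.34) were higher in the head. Ltf (-5.48 ± 0.46), the carbonic anhydrase genes Car4 (-4.11 ± 0.37) and Car2 (-2.57 ± 0.30), neuropeptide Npy (-3.97 ± 0.35) and Cd36 (-2.92 ± 0.46) were higher in the tail. 3 of 13 uterine hormone response genes were lower (3 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.14 with an estimated correlation), namely Ltf, Car2 and Igf1 (-1.09 ± 0.19), a call missed with all probes of the list (adjusted p = 0.081). 5 of 21 extracellular matrix genes were lower (5 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.57 with an estimated correlation), with Fn1 (-1.45 ± 0.29). limma called 556 of 8638 probes, 190 higher and 366 lower, while only these arrays gave 2544. Adjusted p was at most 0.00016 for genes with an SE. The count was 240 without epididymis head replicate 1, 285 without epididymis head replicate 2, 302 without epididymis tail replicate 1 and 254 without epididymis tail replicate 2.

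Hair in anagen, its growth phase, was compared with catagen, its regression (2 arrays each). The pigment cell gene Mlana (2.74 ± 0.30), the Wnt pathway transcription factor Lef1 (2.33 ± 0.37) and the hair shaft genes Krtap1-5 (2.32 ± 0.41), Krt81 (2.12 ± 0.21) and S100a3 (2.28 ± 0.36) were higher in anagen. Pdk1 (-5.96 ± 0.43), Wfdc18 (-2.89 ± 0.34) and Ltf (-2.76 ± 0.46) were lower. 7 of 10 hair shaft and melanocyte genes were higher (7 adjusted over the list alone, camera adjusted p = 1e-25). 8 of 13 macrophage genes were lower (9 adjusted over the list alone, camera adjusted p = 1e-11), with Ctss (-1.78 ± 0.35), C1qc (-1.51 ± 0.22) and Fcgr2b (-1.39 ± 0.23). Muscle genes were lower in the same arrays: 5 of 11 genes were lower (8 adjusted over the list alone, camera adjusted p = 7e-10), with Eno3 (-1.66 ± 0.25) and Tnnc2 (-1.69 ± 0.36). 7 of 28 cell cycle genes were higher (12 adjusted over the list alone, camera adjusted p = 2.3e-08). limma called 428 of 8638 probes, 191 higher and 237 lower, against 404 and 364 after quantile normalization, while only these arrays gave 2436. The genes given had adjusted p up to 0.0011. The count was 142 without hair anagen replicate 2, 138 without hair catagen replicate 1 and 129 without hair catagen replicate 2. Without hair anagen replicate 1 it was 38.6% of the full count.

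Bladder on postnatal day 1 was compared with adult bladder (2 arrays each). The elastic fibre genes Eln (2.94 ± 0.34) and Mfap5 (2.15 ± 0.50), the collagen crosslinking enzyme Lox (2.51 ± 0.44) and the growth factor gene Igf2 (2.66 ± 0.44) were higher, with 0.75 for another Igf2 probe. The antigen presentation genes H2-Aa (-4.59 ± 0.40), H2-Q8 (-2.38 ± 0.24) and H2-D1 (-1.76 ± 0.19) were lower. 10 of 21 extracellular matrix genes were higher (14 adjusted over the list alone, camera adjusted p = 3.6e-20). 6 of 11 antigen presentation genes were lower (6 adjusted over the list alone, camera adjusted p = 7.4e-17). 8 of 28 cell cycle genes were higher (10 adjusted over the list alone, camera adjusted p = 3.3e-16), with Racgap1 (1.98 ± 0.25) and Mcm6 (1.59 ± 0.24). 2 of 8 smooth muscle genes were higher (4 adjusted over the list alone, camera adjusted p = 3.5e-06). limma called 406 of 8638 probes, 161 higher and 245 lower, against 411 and 662 after quantile normalization, while only these arrays gave 29. For these genes adjusted p reached 0.0023 at most. The count was 255 without bladder P1 replicate 1, 200 without bladder P1 replicate 2 and 146 without bladder adult replicate 2.

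Small bowel at embryonic day 16.5 (2 arrays) was compared with adult duodenum, jejunum and ileum (6 arrays). The endocytic gene Mamdc4 (5.96 ± 0.47), known from the suckling gut, the imprinted Igf2 (4.19 ± 0.36) and Grb10 (3.77 ± 0.30), and the urea cycle enzyme Ass1 (3.98 ± 0.28) were higher in the embryo. Pigr (-6.82 ± 0.39), the antimicrobial lectin gene Reg3b (-4.83 ± 0.34), Cyp3a11 (-6.09 ± 0.50), Cyp2b10 (-4.54 ± 0.27) and Arg2 (-3.93 ± 0.21) were lower. 10 of 11 antigen presentation genes were lower (10 adjusted over the list alone, camera adjusted p = 3e-07), with H2-Aa (-3.89 ± 0.32). 11 of 18 enterocyte genes were lower (11 adjusted over the list alone, camera adjusted p = 1.9e-05, adjusted p = 0.11 with an estimated correlation), including Apob (-2.23 ± 0.20), the alkaline phosphatase Alpi (-2.08 ± 0.37) and Car4 (-2.30 ± 0.30). 21 of 28 cell cycle genes were higher (22 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.7e-06), with Mcm6 (1.90 ± 0.19) and H2az1 (2.06 ± 0.18). 8 of 13 ribosomal protein genes were higher and 1 lower (8 and 2 adjusted over the list alone, camera adjusted p = 2.9e-05), Rpl23 (1.61 ± 0.13) and Rpl3 (1.49 ± 0.14) among them. limma called 4330 of 8638 probes, 2041 higher and 2289 lower. Of the genes given, the weakest had an adjusted p of 2.1e-06. With the array series as a block the count was 1659, and 268 of the calls turned sign.

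**Figure D4:**
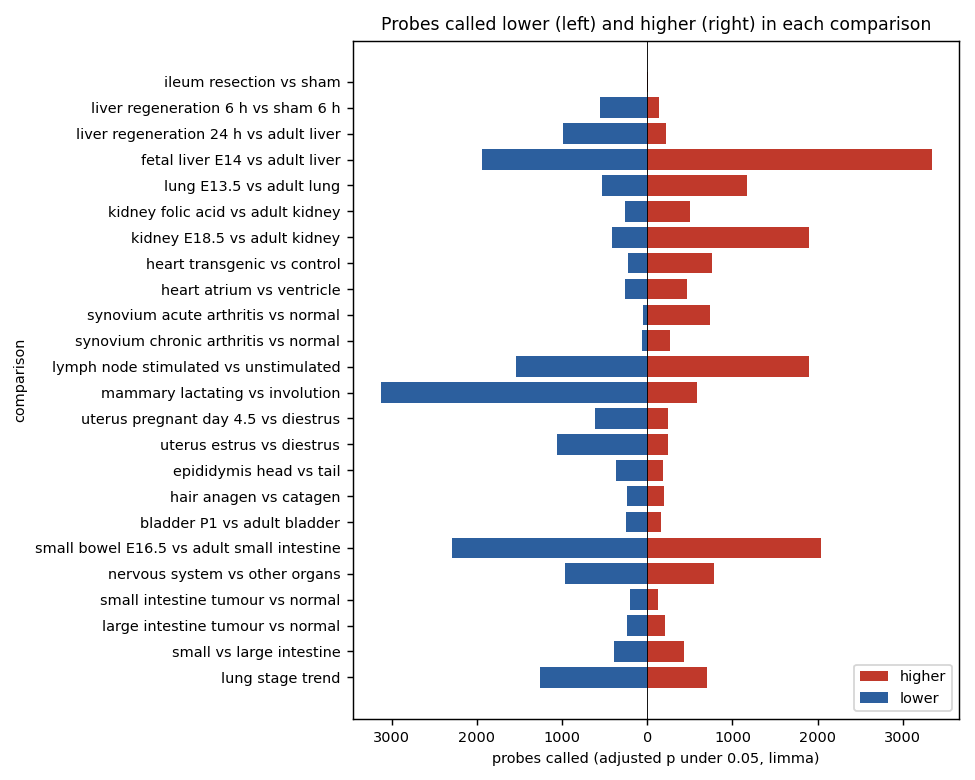
Probes called at adjusted p under 0.05 (limma) in each comparison, higher to the right and lower to the left, with values as deposited. The counts ran from 14 after ileum resection to 5282 in fetal liver, and the split of lactating against involuting mammary gland, 588 and 3131, became 2475 and 2299 with array medians centred.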

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

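All tests of the fetal liver, lymph node and mammary patterns were chosen after the result was seen. The splits of sources into other groups were planned.

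In fetal liver, probes named for Tmem185a, Mrps18b, Timm17a and Kansl3, genes of general cell functions, and for Dipk1b rose as far as red cell genes. A globin transcript reported by these probes was tested through their correlation with Hba-a1 over the other 87 sources, and the median r of the 5 was 0.90. The r of 0.13 argues against a globin transcript for Dipk1b, while for the other 4 it is a candidate explanation, with blood mononuclear cells at mean log2 ratios of 10.64, 9.64, 8.26 and 7.94. Second probes of Mrps18b and Kansl3 did not follow (highest 0.49 as deposited), but 812 of 2228 probe pairs of 1 gene (36.5%) had r below 0.3 here. A rise of the named genes themselves and a globin signal cannot be told apart, since second probes so often differ, and fetal blood formation stays open as the biology of both.

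Between stimulated and unstimulated lymph node 3445 probes were called. The array lot as the whole cause is argued against by the lot as a block, which gave 3438 calls, 3177 of them shared, while the lot itself moved 3469 of 8638 probes over the 22 sources with 2 lots. With the finer array series as a random block the count was 3246, but both unstimulated arrays lie in 1 series, so series and stimulation cannot be told apart. The stimulation itself also stays open.

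Of the calls between lactating and involuting mammary gland 588 were higher and 3131 lower. Centring each array on its median gave 51.8% higher, but centring pulls a split towards balance by its construction, so this decides nothing. After quantile normalization 614 calls were higher and 982 lower, 38.5% higher, and 546 calls turned sign. The scaling of the arrays and a real shift of most transcripts in lactation cannot be told apart, since nothing measured here fixes the total RNA of a tissue, and the biology stays open.

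For nervous tissue only the real of 100 splits had as many calls (1748, others at most 532), too few to exclude chance. For large intestine tumours 1 of 35 splits did (448, others at most 1), too few to exclude chance. For small intestine tumours 4 of 100 splits drawn did (real 329, highest other 1898), of 286 possible, a share too near 0.05 to exclude chance firmly, and a first draw had held fewer splits as large. The real count was 26 without duodenum. Calls several times the real count point to a structure of the samples beside the tumours. The highest places Jej3 with duodenum and proximal jejunum, and proximal jejunum 46 with the tumours, while another, with 1252, keeps all sources of the # title form on 1 side. For small against large intestine chance cannot be excluded in this way, since 2 of 35 splits gave as many as the real 850 (with 1 mean per side), the highest other being 1062, which moves proximal jejunum 46 to the large intestine side. Proximal jejunum 46 has the # title form, and sources without it gave 410 calls.

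Single sources stood apart in 8 of 68 groups of values, where chance alone gives about 1 in 20. Dorsal root ganglion had Map2 at 2.20 (nearest nervous source 3.84) and H2-Aa at 0.48 (nearest -1.97). Striatum had Ces1c at -4.19 (nearest -2.43). Ly6d was 3.67 in Jej3 (nearest tumour 2.30), and Jej1 had Cyp3a11 at 5.02 (nearest 3.84) and Sult1d1 at 2.14 (nearest 1.53). Hao2 was 1.46 in Col1 (nearest 0.90), and Ces1d -1.98 in Col2 (nearest -0.15).

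The tumour effect differed between small and large intestine for 63 of 8494 probes (limma, 39 higher in small intestine, 24 lower). Hao2 differed by 4.26 ± 0.38 (0.38 in small and -3.88 in large intestine, adjusted p = 2.5e-06), Guca2a by 3.77 ± 0.55 (-0.08 and -3.86, adjusted p = 0.0011), Hsd3b1 by 2.78 ± 0.39 (-0.12 and -2.90, adjusted p = 0.00099) and Sult1d1 by 2.10 ± 0.45 (-1.74 and -3.84, adjusted p = 0.025). In normal tissue Hao2 (-5.10) and Guca2a were already lower in small than large intestine, so baselines differ. Fam210a differed by -1.88 ± 0.33 (0.72 and 2.60, adjusted p = 0.0074) and Gcnt2 by -2.17 ± 0.50 (1.11 and 3.28, adjusted p = 0.041).

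Acute and chronic arthritis differed directly for 94 of 8638 probes (limma, 83 higher in acute, 11 lower). Angptl4 was 2.48 ± 0.28 and Fcgr2b 1.97 ± 0.23 higher in acute (adjusted p = 6.7e-10 for each), Cd14 2.21 ± 0.44 and Ctss 1.74 ± 0.35 (adjusted p = 0.00094 for each), Postn 1.18 ± 0.32 (adjusted p = 0.037) and Cfb 1.09 ± 0.28 (adjusted p = 0.024). Mgat2 differed by -0.86 ± 0.21 (adjusted p = 0.019) and Eno3 by -1.18 ± 0.25 (adjusted p = 0.003). Both belong to the 10 lowest acute genes, which lost calls without an array.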

How the results depend on the processing

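No paired analysis was possible by replicate number for tumours against normal intestine or the array comparisons, because the groups share none in the labels. In 8 array comparisons each of 2 array series holds 1 array of each group, so the series as a block pairs them; their deviations correlated with r from 0.11 to 0.81, and all 8 counts stayed within 1.5 times. The numbers 43, 48, 59 and 72 recur in tumour names but in no normal source, and as a random block they gave 329 calls for small and 447 for large intestine tumours. For the difference of tumour effects between small and large intestine, 63 calls, tumours of both organs share the numbers 1, 2, 43 and 72. With these 4 and 48 and 59 as a random replicate block 76 were called (63 of them shared), with 43, 48, 59 and 72 alone 64, and with the number as a fixed replicate block 446 (60 shared). Deviations of tumours with a shared number correlated with r from -0.41 to 0.43, and 0 of 4 colon tumours correlated best with its own number, so the numbers were not taken to pair the tumours. Chosen after the data were seen were these blocks for the difference, the tests with the array series as a fixed or random block, those without the tumours Duo48 and Jej59 or without spinal cord and dorsal root ganglion, and leaving out each colon tumour or, against large intestine, each small intestine source. With the array lot as a block or the probes of a gene averaged, all counts stayed within 1.5 times in the 20 and 24 comparisons run, and centring array medians moved 1 of 24 as far, to 703 in liver 24 h. Of 706 named gene results 694 kept their call with centring and 638 with quantile normalization, and of 178 list calls 172 and 147. The counts below are probes called by limma where they moved by over 1.5 times, and the cause was not tested except as stated. After quantile normalization they were 0 for ileum (233 at an unadjusted p under 0.05), 19 for liver 6 h, 106 for liver 24 h, 2613 for lung E13.5, 1253 for folic acid kidney, 3847 for kidney E18.5, 140 for transgenic heart, 1548 for acute arthritis, 649 for chronic arthritis, 2102 for lymph node, 1596 for mammary gland, 1435 for pregnant uterus, 768 for hair, 1073 for bladder, 3111 for lung trend, 181 for small intestine tumours, 1168 for large intestine tumours and 1268 for small against large intestine, and in mammary gland 546 calls turned sign. With probes measured on every array, and so fewer probes tested, they were 2614 for fetal liver, 839 for lung E13.5, 463 for folic acid kidney, 1237 for kidney E18.5, 415 for transgenic heart, 2242 for lymph node, 2232 for mammary gland, 245 for pregnant uterus, 410 for estrus, 254 for hair, 258 for bladder, 2227 for small bowel E16.5 and 970 for lung trend. With only the arrays compared, and so fewer arrays to estimate the spread, they were 0 for ileum (231 at an unadjusted p under 0.05), 0 for liver 6 h (1242 at an unadjusted p under 0.05), 110 for liver 24 h, 622 for lung E13.5, 2 for folic acid kidney, 1188 for kidney E18.5, 19 for transgenic heart, 6 for atrium, 4722 for acute arthritis, 1116 for chronic arthritis, 622 for lymph node, 5765 for mammary gland, 2544 for epididymis, 2436 for hair and 29 for bladder. With AF arrays alone they were 1 for ileum, 637 for lung E13.5, 227 for folic acid kidney, 853 for kidney E18.5, 109 for transgenic heart, 348 for atrium, 93 for bladder and 1136 for lung trend. The series as a block gave 290 for liver 6 h and 1659 for small bowel E16.5; for lymph node it could not be fitted. With arrays as the unit and the source as a random block they were 775 for small intestine tumours, 732 for large intestine tumours and 1407 for small against large intestine. Without the title form as a covariate they were 156 for small intestine tumours and 461 for small against large intestine, with sources outside the # form 72 for large intestine tumours and 410 for small against large intestine, with sources of the # form 13 for small intestine tumours (against 1 normal source), and with ileum added to normal small intestine 851 for small intestine tumours. Leaving out 1 array or source at a time gave 2 to 15 for ileum, 224 to 805 for liver 6 h, 492 to 830 for liver 24 h, 4119 to 4659 for fetal liver, 1040 to 1409 for lung E13.5, 473 to 625 for folic acid kidney, 1368 to 2332 for kidney E18.5, 359 to 1120 for transgenic heart, 59 to 1353 for atrium, 367 to 460 for acute arthritis, 141 to 189 for chronic arthritis, 2496 to 3016 for lymph node, 2591 to 2992 for mammary gland, 139 to 679 for pregnant uterus, 521 to 1241 for estrus, 240 to 302 for epididymis, 129 to 1.7e+02 (rounded) for hair, 146 to 373 for bladder, 3057 to 4312 for small bowel E16.5, 1506 to 1955 for lung trend, 1383 to 1622 for nervous system, 26 to 1130 for small intestine tumours, 192 to 365 for large intestine tumours and 418 to 1179 for small against large intestine. Turned in direction were Uqcrc2 in lymph node with probes averaged (0.22, adjusted p = 0.16), Myl7 in atrium against ventricle without atrium replicate 1 (-0.42, adjusted p = 0.84, against at most 3.52 without another array), and the uterine hormone response list in pregnant uterus after quantile normalization (adjusted p = 0.93). With 2 arrays in most groups, small changes could be missed, and signal over background is not given in the sources.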

Other observations

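Some marker lists were high outside their organ, given as mean log2 ratio with the SD of both arrays. The erythroid list reached 2.13 ± 0.09 in spleen, beside 2.10 ± 0.05 in fetal liver, and 1.08 ± 0.04 in blood mononuclear cells. The epidermis list was at 2.19 ± 0.05 in normal synovium, against 2.62 ± 0.04 in skin of postnatal day 2. The skeletal muscle list reached 2.06 ± 0.08 in thyroid and 2.43 ± 0.05 in catagen hair, beside 1.27 ± 0.00 in anagen hair.

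The Paneth and regenerating islet-derived list was highest in the 3 kinds of ileum, with 4.69 ± 0.24 after sham operation, 4.36 ± 0.33 after resection and 4.33 ± 0.44 in untreated ileum, and 2.98 ± 0.39 in proximal jejunum. The acute phase list was at 3.12 ± 0.27 in liver 24 h into regeneration, 2.99 ± 0.43 at 6 h, 2.39 ± 0.04 after sham operation and 1.87 ± 0.09 in adult liver. These lists were fixed beforehand, but the sources were chosen after the values were seen, and no difference was tested here.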
